A study of Mus musculus with 9 samples.

How the data were processed

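Mature olfactory sensory neurons of mice carrying Olfr73-IRES-GFP, Olfr1507-IRES-GFP or Olfr160-IRES-mCherry were dissociated with papain from the main olfactory epithelium and sorted by the authors for high GFP or mCherry and low DAPI. Libraries were made from polyadenylated RNA with a low-input kit, 3 per group and 9 in all. The labels do not say whether the 3 came from separate animals, and the series description speaks of duplicates while 3 libraries per group are deposited. The sequence of the reporters is not in the deposited tables, so reporter transcripts were not analysed here.

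Per the labels, the authors aligned reads to mm10 with STAR 2.6.1 and quantified genes with RSEM 1.3.1, and listed DESeq2 without a version. The annotation release was not given in the sources used here. The deposited values are RSEM expected counts per gene and, in a second table, TPM (transcript abundance scaled for length and depth) scaled by the authors to the same sum in each library. In the expected counts 4.06% to 5.54% of the values of a library were not whole numbers. The tables hold 55291 genes, 1408 of them with symbols beginning with Olfr. Coordinates were taken from GENCODE release M21, in which 98.7% of the transcript identifiers of the tables were found with their version. The columns carry older names of the receptors, and the match of columns to groups was checked by the counts of the tagged receptors. Libraries held 17212807 to 36230606 counts, so that 3 counts, the floor used for a count of 0, correspond to 0.0828 to 0.174 CPM per library. Such floors and the Wilson intervals, at 95%, cover counting error only.

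Expected counts were rounded and tested with edgeR 4.0.16 in R 4.3.3, with filterByExpr by group (16399 genes kept), TMM normalisation and a robust quasi-likelihood F test on all 9 libraries with a means model by group. The Benjamini-Hochberg adjusted p threshold was 0.05. The 3 pairwise comparisons, the test over all groups and the genes set apart in each group came from this fit. The SE of a log2 fold change is its size divided by the square root of F. Changes in 28 fixed gene lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over all lists and comparisons, with an estimated correlation and fry as alternatives. DESeq2 1.42.0 served as an alternative test. Scipy 1.17.1, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 ran under Python 3.11.15. A fold against a group with 0 counts was bounded with 3 counts over the group, and against 1 to 3 counts a ratio with its counting interval was given.

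The gene lists, the tests of the comparisons, the alternatives named first below and the rule for naming genes were fixed before the data were examined, while the tests of explanations other than splits of the samples were written after the receptor shares were seen. For each comparison the rule took the 8 genes with the largest change each way among those past the threshold with a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups, leaving out Olfr genes, gene models and markers of other cells. It added up to 3 members of each list with the lowest adjusted p, up to 3 other Olfr genes per group, and, whatever their test, the tagged receptors and Omp, Adcy3, Nqo1, Ncam2, Nrp1, Nrp2, Plxna1, Robo2, Kirrel2, Kirrel3, Epha5, Efna5, S100a5 and Atf5. It gave 333 values of 201 genes. The text names part of these, chosen after their values were seen, and the effect of the alternatives is given for all 333. Results for some single genes are not reported here.

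Alternatives fixed beforehand were RLE size factors, library size alone, Olfr genes left out, no low-count filter, a filter of 5 CPM in 3 libraries, DESeq2, limma-voom, limma-trend on TPM with pseudocounts of 1 and 0.1, unrounded counts, the replicate number as a block, only the 6 libraries compared, an adjusted p of 0.01, a minimum absolute log2 fold change of 1, glmTreat against 2-fold, and leaving out each library. Chosen after seeing the data were Olfr160 library 3 alone, scaling to the olfactory transduction list, and thinning to equal depth. The fit was tested on data simulated from the mean levels and the spread over all 9 libraries, with 200 genes changed in Olfr1507. Compared with Olfr160, 24% of genes changed 2-fold and 35% of genes changed 4-fold were called, with 5 false calls among 64. The comparison of Olfr73 with Olfr160 in the same data, without a simulated change, gave 0 calls. Camera called the simulated raised list and 0 others. Genes were simulated independently of each other, so this run could not show how camera behaves with correlated genes.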

Results

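Polyadenylated RNA was sequenced from mature olfactory sensory neurons, the odorant-detecting neurons of the nose, sorted from the main olfactory epithelium of mice. Each such neuron transcribes a single odorant receptor gene (symbols beginning with Olfr) at a high level, and the mice carried a receptor allele whose transcript also encodes a fluorescent protein. GFP was joined to Olfr73 or to Olfr1507 and mCherry to Olfr160, so fluorescence marked neurons that had chosen the tagged allele, and these were collected by flow cytometry. The groups are called Olfr73, Olfr1507 and Olfr160 after the tagged allele. Each held 3 libraries, 9 in all. The 3 Olfr73 libraries held 21278859, 20805071 and 20394345 expected counts, the Olfr1507 libraries 21982040, 36230606 and 21031793, and the Olfr160 libraries 17212807, 22590535 and 20735684. Genes with at least 10 counts numbered 14858 ± 323 per library in Olfr73, 12770 ± 794 in Olfr1507 and 16477 ± 467 in Olfr160 (mean ± SD, n = 3). Group levels below are normalised CPM (counts scaled by the effective library size), given as mean ± SD with n = 3 libraries, and log2 fold changes carry a standard error (SE). The labels do not say whether the libraries of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

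The tagged receptor had the most counts of all Olfr genes in each library of its own group, but its share of receptor counts differed between the groups. In Olfr160 library 1 it had 3131 counts and the next gene, Olfr523, 2106. Olfr1507, on chromosome 14 from 52488791 to 52495749 (mm10), stood at 2994 ± 275 normalised CPM in its own group, 35.5 ± 22.8 in Olfr73 and 72.2 ± 12.6 in Olfr160. Olfr73, on chromosome 2 from 88032288 to 88037699, stood at 870.5 ± 109 in its own group, 1.04 ± 0.615 in Olfr1507 and 0.776 ± 0.210 in Olfr160. Olfr160, on chromosome 9 from 37708964 to 37716250, stood at 423 ± 294 in its own group, 0.541 ± 0.185 in Olfr1507 and 2.14 ± 2.97 in Olfr73. Of all counts on Olfr genes, the tagged receptor took 90.5 ± 4.87% in the Olfr1507 libraries, 26.4 ± 5.58% in the Olfr73 libraries and 5.58 ± 4.11% in the Olfr160 libraries. The 3 Olfr160 libraries differed among themselves, at 2.08% in library 1 (95% Wilson interval 2.01 to 2.16), 4.54% in library 2 (4.45 to 4.63) and 10.1% in library 3 (9.96 to 10.3). These intervals cover counting error only, because amplified reads without molecular identifiers are not independent molecules. Each pair of groups differed in this share with an exact two-sided permutation p of 0.1, the smallest that 3 libraries against 3 allow. With TPM, the length-scaled values of the authors, in place of counts the mean share in Olfr73 rose to 47.2%, while the Olfr160 libraries fell to 1.22%, 2.76% and 6.33%. Other Olfr genes with at least 10 counts numbered 119 ± 95.6 per library in Olfr1507, 445 ± 95.3 in Olfr73 and 754 ± 91.0 in Olfr160. The most abundant of them were Olfr523 at 99.97 ± 11.99 CPM, Olfr1349 at 98.2 ± 60.4 CPM and Olfr1348 at 83.6 CPM in Olfr160. In Olfr73 they were Olfr1349 at 57.3 ± 90.3 CPM, Olfr169 at 47.1 CPM and Olfr523 at 45.6 ± 51.4 CPM, and library 2, with 3451 counts, carried most of Olfr1349. In Olfr1507 they were Olfr1372-ps1 at 40.5 ± 11.3 CPM, Olfr1206 at 13.6 ± 15.6 CPM and Olfr1280 at 11.4 ± 17.02 CPM, and library 2 carried the last 2. Reads shared between related Olfr genes can move between them in the authors' counting, so the single Olfr values other than those of the tagged genes are uncertain.

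**Figure D1:**
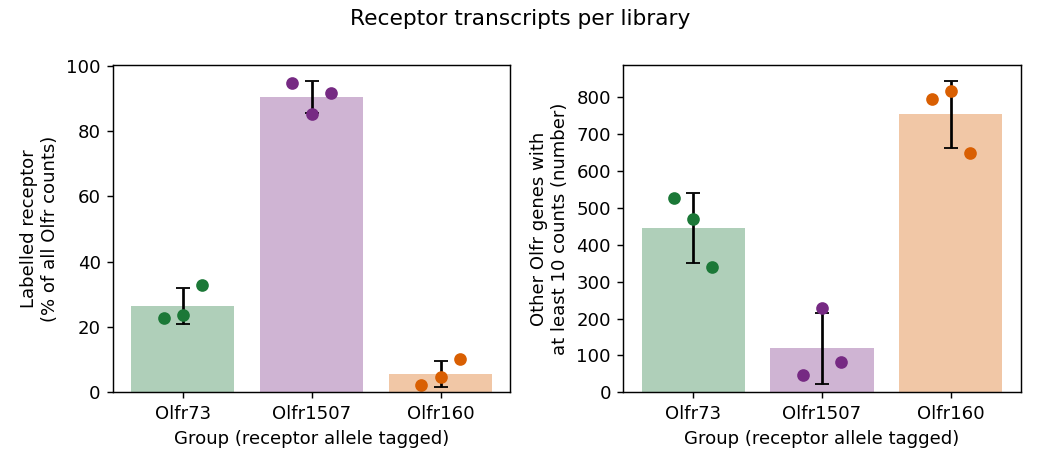
Left, the percent of all Olfr counts that fell on the tagged receptor, and right, the number of other Olfr genes with at least 10 counts, for each library (points), with the group mean (bar) and SD (error bar, n = 3). The share was above 85% in each Olfr1507 library and between 2.08% and 10.1% in the Olfr160 libraries.

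Most lists of markers of other cells took the largest share of counts in Olfr160 and the smallest in Olfr1507, whereas microvillar and brush cell markers took 0.0450% in Olfr160, 0.0110% in Olfr73 and 0.0128% in Olfr1507. Counts on the sustentacular and gland cell list made up 4.67% of the Olfr160 libraries, 0.879% of the Olfr73 libraries and 0.293% of the Olfr1507 libraries (means, n = 3). Respiratory epithelium markers made up 0.877%, 0.198% and 0.0182%, and immune cell markers 0.0810%, 0.0165% and 0.000600%, in the same order of groups. The respiratory share had an SD of 0.540% over the Olfr160 libraries, where libraries 2 and 3 stood at 0.588% and 0.544% and library 1 above them. The olfactory transduction list, genes of the neurons' own signalling cascade, took 4.82% of counts in Olfr160, 6.85% in Olfr73 and 10.2% in Olfr1507. Because the groups differed this much in composition, the scaling of the libraries matters. With scaling by trimmed mean of M values (TMM), the median log2 fold change of all tested genes was -0.14 for Olfr1507 over Olfr160, -0.15 for Olfr1507 over Olfr73 and -0.012 for Olfr73 over Olfr160. With library size alone these medians were -0.56, -0.47 and -0.12. Libraries scaled instead to the olfactory transduction list, an alternative chosen after seeing the data, gave -1.43, -0.88 and -0.58. Changes below are relative to the TMM scaling.

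**Figure D2:**
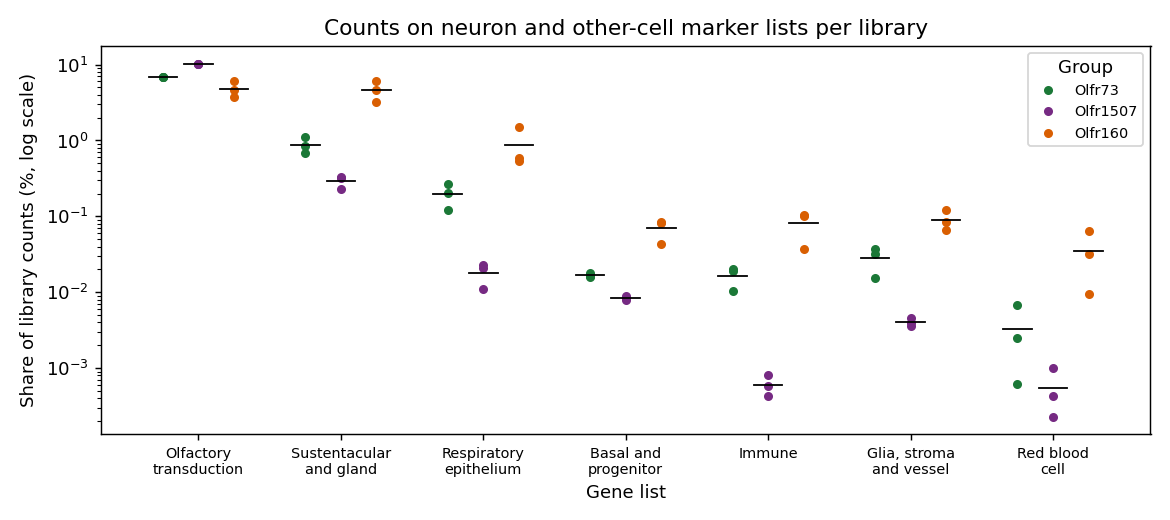
Share of each library's counts (percent, log scale) on the olfactory transduction list and on 6 lists of markers of other cells. Points are libraries, colours are groups and horizontal lines are group means (n = 3). The Olfr160 libraries had the highest mean share on the sustentacular and gland list (4.67%) and the lowest on the transduction list (4.82%).

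The comparison of Olfr1507 with Olfr160 asked how libraries sorted on these receptors differ in the rest of their transcriptome. The groups also differed in the reporter, GFP against mCherry, and in the mice that carried it. The tagged receptor took 90.5% of Olfr counts in Olfr1507 and 5.58% in Olfr160. Levels in Olfr160 are thus those of mixed libraries, and a difference cannot be assigned to receptor identity alone. Of 7 tested genes of the dorsal zone list 3 were lower in Olfr1507, 2 were higher and 2 did not pass. Nqo1, a quinone reductase used as a dorsal zone marker (chromosome 8, 107388225 to 107403206), stood at 4.19 ± 3.17 normalised CPM in Olfr1507 and 731 ± 315 in Olfr160, a log2 fold change of -7.39 (SE 0.61, edgeR adjusted p = 2.96e-05). Acsm4, an acyl-CoA synthetase of the same zone (chromosome 7, 119690026 to 119714565), stood at 5.74 ± 3.11 against 402 ± 126, and Robo2, an axon guidance receptor for Slit proteins (chromosome 16, 73891839 to 74411825), at 11.5 ± 5.54 against 233 ± 80.7. Nrp2, a semaphorin receptor of ventral axons (chromosome 1, 62703285 to 62818695), went the other way, at 134 ± 3.53 in Olfr1507 and 29.3 ± 5.07 in Olfr160 (log2 fold change 2.19, SE 0.30, edgeR adjusted p = 0.000423). In all, 7939 of 16399 tested genes passed an edgeR adjusted p of 0.05, 3399 higher in Olfr1507 and 4540 higher in Olfr160. The part higher in Olfr1507 depended on the scaling, 42.8% with TMM, 17.7% with library size alone and 1.60% with transduction-list scaling.

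Adhesion and activity-dependent genes changed in both directions. Calb2, the calcium-binding protein calretinin (chromosome 8, 110137502 to 110168210), stood at 5771 ± 717 in Olfr1507 and 313 ± 13.3 in Olfr160, and S100a5, another calcium-binding protein, at 5.12 ± 2.59 against 206 ± 58.9. The adhesion molecule Kirrel3 (chromosome 9, 34485894 to 35036716) stood at 556 ± 43.6 in Olfr1507 and 89.9 ± 33.9 in Olfr160, whereas its relative Kirrel2 (chromosome 7, 30447534 to 30457690) stood at 221 ± 158 against 1695 ± 499. The ephrin Efna5 was higher in Olfr1507 (log2 fold change 2.04, SE 0.38, edgeR adjusted p = 0.00236) and its receptor Epha5 was lower (-1.48, SE 0.36, edgeR adjusted p = 0.00797). Pcdh9, Lrrc3b and Pcdh17 were lower in Olfr1507, with log2 fold changes of -5.61, -6.02 and -2.76. Of the 34 tested members of the local sorting and adhesion list, 13 were higher in Olfr1507, 15 were lower and 6 did not pass. This balance depended on the scaling, with 10 higher and 16 lower with library size alone and 3 higher and 23 lower with transduction-list scaling. Of the 7 activity-dependent genes, 1 was higher and 4 were lower. Among anterior-posterior guidance genes 3 of 12 were higher in Olfr1507 and 8 were lower, including Sema3a (log2 fold change -3.40), Plxna1 (-1.70) and Nrp1 (-1.18).

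Genes of the neurons' signalling and cilia were higher in Olfr1507. Of 23 tested olfactory transduction genes, 18 were higher in Olfr1507 and 2 were lower, with a median log2 fold change of 1.35. Among the higher ones were the cyclic nucleotide-gated channel gene Cnga2 (1.80), the channel modulator gene Stoml3 (1.87) and the adenylyl cyclase gene Adcy3 (1.60). Omp, the marker of mature olfactory neurons, was also higher (1.13). With library size alone 16 members were higher and 2 lower. Genes of intraflagellar transport and of the BBSome, which carry cargo in cilia, were higher for 27 of 33 members and lower for 0 (22 and 0 with library size alone, 0 and 9 with transduction-list scaling), with a median of 0.93, and Ift172 is an example at 1.08. Of 32 genes of the unfolded protein response, 15 were higher and 3 were lower (9 and 4 with library size alone, 1 and 17 with transduction-list scaling), with Herpud1 at 1342 ± 116 in Olfr1507 and 336 ± 20.2 in Olfr160, and Trib3 (1.63) and Atf5 (1.64) also higher. Of 12 heat shock genes 6 were higher and 5 lower (1 and 8 with transduction-list scaling), and Hmox1 (2.55) was among the higher ones. Synapse and neuromodulator genes were higher for 11 of 23 and lower for 5 (7 and 6 with library size alone, 2 and 10 with transduction-list scaling), including the calcium channel gene Cacna1b (1.70) and the dopamine receptor gene Drd2 (1.55). Ion channels of excitability went both ways, 9 higher and 6 lower of 24, with Scn9a at 0.93 and Ano6 at -2.44, but 5 higher and 9 lower with library size alone and 0 higher and 16 lower with transduction-list scaling. With transduction-list scaling, the medians of the cilia, unfolded protein response and synapse lists turned to -0.33, -0.69 and -0.43. Ift172 and Scn9a turned to -0.18 and -0.33. Omp turned to -0.094, but it belongs to the list used for scaling, so its value there is partly set by construction.

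Immediate early genes and most markers of other cells were lower in Olfr1507. Of 25 immediate early genes, 0 were higher and 16 were lower, among them Arc (2.52 ± 0.519 against 45.4 ± 15.6), Ier3 (1.26 ± 0.318 against 55.6 ± 21.05) and Zfp36 (19.8 ± 6.73 against 499.6 ± 199). From library 1 to library 3 of Olfr160 the median log2 ratio of this list was -0.76, beside -0.82 for sustentacular and gland markers. It was -0.11 for glia, stroma and vessel markers and -0.55 for symbols beginning with Rpl or Rps. These ratios rest on 1 library over 1 other, and the source of the immediate early transcripts was not tested. Sustentacular and gland markers were lower for 24 of 26, with Cyp2g1 at 63.3 ± 31.8 in Olfr1507 and 4343 ± 1076 in Olfr160 and Sec14l3 at 130.2 ± 39.4 against 8210.5 ± 2212. Basal and progenitor markers were lower for 13 of 16, including Neurod1 (log2 fold change -6.77) and Top2a (-6.09). Microvillar and brush cell markers were lower for 8 of 11, respiratory markers for 7 of 10, immune markers for 19 of 19, red blood cell markers for 7 of 7 and markers of glia, stroma and vessels for 15 of 16. Members called higher in Olfr1507 were 2 respiratory, 1 microvillar and brush, 1 sustentacular and gland, 1 basal and progenitor and 1 glia, stroma and vessel marker. Csf1r, the macrophage growth factor receptor, had 0 counts in the Olfr1507 libraries and was at least 559-fold lower there, taking 3 counts over the group as the floor. By the same floor Mpo was at least 244-fold, Azgp1 at least 225-fold, Fat2 at least 169-fold and Fcrls at least 165-fold lower in Olfr1507. The genes with the largest fold changes in favour of Olfr1507 included Twist2 (log2 fold change 5.38), Fndc1 (5.01), Unc93a (5.01) and Cemip (4.54).

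The other fixed lists were divided in this comparison. Of 6 ventral zone genes 3 were higher and 1 lower, with a ventral median of 0.69 that turned to -0.64 with transduction-list scaling. Nfia, a transcription factor of the ventral list, was 0.68 higher (edgeR adjusted p = 0.00768) but passed neither with library size alone (adjusted p = 0.237) nor with TPM, and it turned to -0.64 with transduction-list scaling. Ncam2, an adhesion molecule of ventral axons, stood at 33.4 ± 4.63 against 17.6 ± 5.79 and did not pass (edgeR adjusted p = 0.0688). Among olfactory transcription factors 3 of 18 were higher and 4 lower (1 and 5 with library size alone, 0 and 14 with transduction-list scaling), and Sp8 (-5.79) was among the lower ones. Immature neuron markers were higher for 6 of 19 and lower for 8 (2 and 11 with library size alone, 0 and 17 with transduction-list scaling), including Tubb3 (-1.72). Of 57 clustered protocadherins 5 were higher and 1 was lower, with Pcdha12 at 1.33 and Pcdhgc3 at -2.75. With library size alone 4 were higher and 10 lower, and with transduction-list scaling 0 were higher and 46 lower. These are related neighbouring genes, and reads from sequence they share can be split between them. The list of symbols beginning with Rpl or Rps, which also holds Rps6k kinases and pseudogenes, was higher for 11 of 112 and lower for 28 (6 and 68 with library size alone, 1 and 92 with transduction-list scaling), with Rps6ka2 at 1.32 and Rps24 at -1.99. Vomeronasal and atypical neuron markers were lower for 12 of 18 and higher for 2, and mitochondrially encoded genes were lower for 2 of 14 and higher for 0. Both of these calls ended without any 1 library of Olfr1507 or Olfr160 (adjusted p 0.0528 to 0.160), and 0 passed when adjusted over the list alone. Of 697 odorant and trace amine receptors 537 were lower in Olfr1507 and 2 were higher. Of 6 tested genes of the list of Y-linked genes and Xist, 2 were lower in Olfr1507, 0 were higher and 4 did not pass. Xist was among the lower ones (-2.37, edgeR adjusted p = 0.00267). Glo1, which varies in copy number between strains, stood at 2022 ± 140.5 against 449.7 ± 57.9, while 4 other strain-variable genes of 10 were lower.

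Adjusted over the list alone, 19 transduction genes, 28 cilia genes and 15 unfolded protein response genes were higher in Olfr1507 and 16 immediate early and 25 sustentacular genes were lower. The median and the mean log2 fold change differed in sign for the heat shock (0.50 and -0.40), transcription factor (0.15 and -0.40), synapse (0.80 and -0.15) and ion channel lists (0.20 and -0.31) and for the list of Y-linked genes and Xist (0.26 and -0.60). Camera, which asks whether a list moves apart from other genes, called 14 of 28 lists here with its preset correlation of 0.01 and 0 with an estimated correlation, where the lowest adjusted p = 0.248. With Olfr160 library 3 alone, the library with the highest share of the tagged receptor, 3337 genes passed, an alternative chosen after seeing the data.

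**Figure D3:**
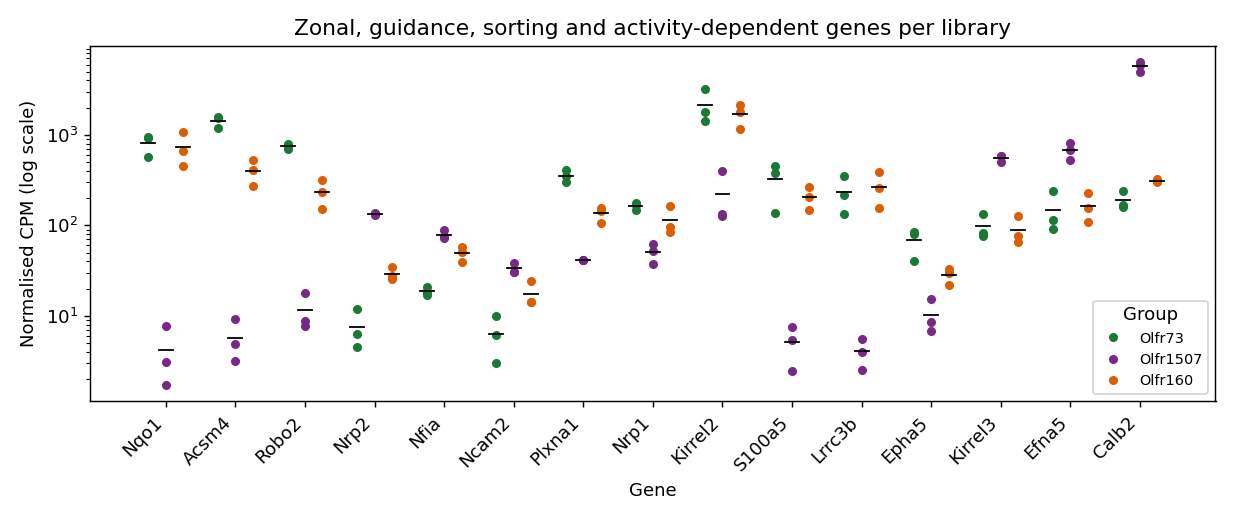
Normalised CPM (log scale) of 15 zonal, guidance, sorting and activity-dependent genes, with libraries as points, groups as colours and group means as horizontal lines (n = 3). Nqo1 had a mean of 4.19 in Olfr1507 and of 811 and 731 in Olfr73 and Olfr160, and Calb2 a mean of 5771 in Olfr1507 and of 189 and 313 in the others.

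The comparison of Olfr1507 with Olfr73, both sorted on GFP, gave 3 dorsal zone genes lower in Olfr1507 and 2 higher of 7, and 5 ventral zone genes higher and 1 lower of 6. These groups too differed in composition. The tagged receptor took 90.5% of Olfr counts in Olfr1507 and 26.4% in Olfr73, and sustentacular and gland markers 0.293% and 0.879% of all counts. Whether RNA from other cells, or from neurons with other receptors, contributed to this comparison was not tested. Acsm4 stood at 5.74 ± 3.11 in Olfr1507 and 1434 ± 204 in Olfr73 (log2 fold change -7.93, SE 0.46, edgeR adjusted p = 9.71e-06). Nqo1 stood at 811 ± 208 in Olfr73 (-7.54, SE 0.61, edgeR adjusted p = 6.47e-05) and Robo2 at 745 ± 48.2 (-6.00, SE 0.40, edgeR adjusted p = 2.43e-05). On the ventral side Nrp2 stood at 134 ± 3.53 in Olfr1507 and 7.59 ± 3.95 in Olfr73 (4.14, SE 0.33, edgeR adjusted p = 6.03e-05). In all, 5640 genes passed, 2379 higher in Olfr1507 and 3261 higher in Olfr73 (42.2% higher in Olfr1507, against 18.2% with library size alone and 5.35% with transduction-list scaling), and without Olfr1507 library 1 the count was 3657.

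The ventral genes higher in Olfr1507 included Nfia (2.08), Nfib (2.06) and Ncam2 (2.39), and the median of the list was above 0 with each of the 4 scalings tried. Guidance genes of the anterior-posterior axis were higher for 2 of 12 and lower for 4 (2 and 7 with library size alone, 2 and 9 with transduction-list scaling), with Plxna1 at 41.6 ± 0.261 in Olfr1507 and 354 ± 52.8 in Olfr73, and with Plxnd1 at 74.5 ± 10.3 against 4.31 ± 2.61. Sema3a (-3.17) and Nrp1 (-1.69) were lower in Olfr1507. Among local sorting genes 8 of 34 were higher and 13 lower (5 and 14 with library size alone, 3 and 20 with transduction-list scaling). Kirrel3 (2.51) and Efna5 (2.20) were higher in Olfr1507, and Kirrel2 (-3.29), Epha5 (-2.76), Pcdh7 (-2.65) and Nphs1 (-5.52) were lower. Of 7 activity-dependent genes 1 was higher and 5 were lower, with Calb2 at 189 ± 44.0 in Olfr73, 4.93 log2 units below Olfr1507, and with S100a5 at 325 ± 166 and Lrrc3b at 236 ± 111 in Olfr73, 5.98 and 5.84 log2 units above it. The genes with the largest changes included Afap1l2, with 1 count in all in Olfr73 and a ratio of 2277 (counting interval 408 to 89988), Unc93a and Zfpm2, at least 181-fold and at least 128-fold higher in Olfr1507, and the adenylyl cyclase gene Adcy5 (69.9 ± 8.16 against 0.295 ± 0.353). Cemip (7.62) was also higher. On the side of Olfr73 were Col27a1, with a ratio of 1552 (278 to 61336), the retinoic acid hydroxylase gene Cyp26b1 (29.0 ± 2.16 against 0.109 ± 0.0944) and Rasgrp4 (660.1 ± 320.1 against 3.69 ± 2.02).

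Transduction genes were higher in Olfr1507 for 11 of 23 members and lower for 1 (10 and 4 with library size alone), with Pde4a (1.73), Stoml3 (1.38) and Adcy3 (1.301) among them. Omp was 0.54 higher (edgeR adjusted p = 0.0383), and this call ended without library 1 or 3 of Olfr73, without any 1 library of Olfr1507 or without Olfr160 library 2 (adjusted p 0.0603 to 0.112), and also with library size alone and with TPM. Cilia genes were higher for 19 of 33 and lower for 1 (9 and 3 with library size alone, 0 and 6 with transduction-list scaling), including Ift46 (0.82). Unfolded protein response genes were higher for 15 of 32 and lower for 0 (9 and 1 with library size alone, 2 and 8 with transduction-list scaling), with Herpud1 (2.07) and Hsp90b1 (1.11). Atf5 of that list was 1.01 higher (edgeR adjusted p = 0.0259), a call that ended without Olfr73 library 1 or 3 or Olfr1507 library 1 (adjusted p 0.0632 to 0.102), and also with library size alone, with TPM and with replicate blocks. Scaled to the transduction list, the medians of the cilia and unfolded protein response lists were -0.27 and -0.21. Omp, itself a member of the list used for scaling, stood at -0.19. Heat shock genes were higher for 6 of 12 and lower for 2, but higher for 1 and lower for 3 with library size alone and higher for 1 and lower for 5 with transduction-list scaling. Synapse genes were divided, 6 higher and 4 lower of 23, with the cannabinoid receptor gene Cnr1 (3.91) and the complexin gene Cplx2 (-1.67) on either side, with 2 higher and 6 lower with library size alone and 2 higher and 10 lower with transduction-list scaling. Ion channels were higher in Olfr1507 for 2 of 24 and lower for 9 (2 and 12 with library size alone, 0 and 16 with transduction-list scaling), including Kcna2 (-1.43). Clustered protocadherins were lower for 12 of 57 and higher for 3 (24 and 1 with library size alone, 38 and 0 with transduction-list scaling), including Pcdhb16 (-1.27).

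Immediate early genes were lower in Olfr1507 for 9 of 25 and higher for 2, with Dusp1 at -1.54. Most markers of other cells were lower as well, sustentacular and gland markers for 22 of 26 and basal and progenitor markers for 12 of 16. Immune markers were lower for 15 of 19, glia, stroma and vessel markers for 11 of 16, respiratory markers for 7 of 10, microvillar and brush markers for 3 of 11 and red blood cell markers for 1 of 7. The last call ended in 7 of the 9 fits without a library (adjusted p 0.0552 to 0.131) and when adjusted over the list alone. Here too 2 respiratory markers and 1 each of the microvillar, sustentacular, basal and glia lists were higher in Olfr1507. Cyp2g1 (-4.02), Sec14l3 (-3.70), Bpifa1 (-3.86), Neurod1 (-4.64), Cd74 (-4.07) and Dcn (-3.59) are examples. Mitochondrially encoded genes were lower for 6 of 14 and higher for 0 (11 and 0 with library size alone), including mt-Co1 (-1.45). Olfactory transcription factors were higher for 4 of 18 and lower for 2 (3 and 4 with library size alone, 1 and 10 with transduction-list scaling), with Tshz1 (1.68) and Rfx4 (2.08) higher. Immature neuron markers were higher for 4 of 19 and lower for 6, with Tuba1a (0.90) and Tubb3 (-1.27) on either side. Symbols beginning with Rpl or Rps were higher for 8 of 112 and lower for 4 (3 and 8 with library size alone, 1 and 21 with transduction-list scaling). Vomeronasal and atypical markers were higher for 1 of 18 and lower for 5, and odorant and trace amine receptors higher for 2 of 697 and lower for 267. Of 6 tested genes of the list of Y-linked genes and Xist, Xist was lower in Olfr1507 (-2.83) and 5 did not pass. Of 10 strain-variable genes Glo1 was higher (2.68) and 4 were lower. Adjusted over the list alone, 13 transduction genes, 23 cilia genes and 16 unfolded protein response genes were higher in Olfr1507. The median and the mean differed in sign for the heat shock (0.31 and -0.16), synapse (-0.041 and 0.073) and ribosomal lists (0.021 and -0.013) and for the list of Y-linked genes and Xist (0.041 and -0.75). Camera called 14 lists with the preset correlation and 0 with an estimated one, where the lowest adjusted p = 0.472.

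The comparison of Olfr73 with Olfr160 gave the fewest calls, 2936 of 16399 genes, with 1222 higher in Olfr73 and 1714 higher in Olfr160 (41.6% higher in Olfr73, against 30.6% with library size alone and 3.96% with transduction-list scaling). A count of calls also falls with the spread between libraries, so it does not measure how alike these groups are. Nqo1 did not differ beyond its error, at 811 ± 208 in Olfr73 and 731 ± 315 in Olfr160 (log2 fold change 0.15, SE 0.45, edgeR adjusted p = 0.846). Acsm4 (1434 ± 204 against 402 ± 126, edgeR adjusted p = 0.00941) and Robo2 (745 ± 48.2 against 233 ± 80.7, edgeR adjusted p = 0.0102) were higher in Olfr73. The ventral genes Nrp2 (-1.95), Nfia (-1.40) and Nfib (-1.37) were higher in Olfr160, as were 5 of the 6 tested members of that list, whose median log2 ratio of Olfr160 library 3 to library 1 was -0.37. Of 7 dorsal genes 2 were higher in Olfr73, with a dorsal median of 0.22 that turned to -0.28 with transduction-list scaling. The number of calls depended on single libraries. There were 1408 without library 1, 976 without library 2, 1878 without Olfr73 library 3, and 61 with Olfr160 library 3 alone, where the spread of the lone library was taken from the other groups. There Acsm4, Robo2, Nrp2, Nfia and Nfib kept their direction but did not pass.

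Several guidance, sorting, activity and transduction genes called in both comparisons with Olfr1507 did not pass here, which does not show that they are unchanged. Kirrel2 (0.35, SE 0.48, edgeR adjusted p = 0.639), Kirrel3 (0.12, SE 0.28, adjusted p = 0.798), Efna5 (-0.15, SE 0.37, adjusted p = 0.807), S100a5 (0.66, SE 0.45, adjusted p = 0.332), Nrp1 (0.51, SE 0.26, adjusted p = 0.199) and Adcy3 (0.30, SE 0.19, adjusted p = 0.312) were among them. Of 34 local sorting genes 6 were higher in Olfr73 and 3 in Olfr160, with Pcdh19 (2.07) and Pcdh9 (-1.93) on either side, and of 7 activity-dependent genes 1 was higher and 1 lower. Calb2 was higher in Olfr160 (-0.73, edgeR adjusted p = 0.0202), Epha5 higher in Olfr73 (1.28, adjusted p = 0.0347) and Ncam2 higher in Olfr160 (-1.47, adjusted p = 0.0323). Each of these 3 calls ended without Olfr160 library 1 or 2 or Olfr73 library 3, those of Calb2 and Epha5 also without Olfr73 library 2, and that of Ncam2 without Olfr73 library 1 or Olfr1507 library 3 (adjusted p 0.0509 to 0.121). Plxna1, a semaphorin coreceptor, stood at 354 ± 52.8 in Olfr73 and 135 ± 24.9 in Olfr160, and 2 of 12 anterior-posterior genes were higher in each group. Clustered protocadherins were higher in Olfr73 for 8 of 57 and lower for 1 (7 and 1 with library size alone, 1 and 1 with transduction-list scaling), including Pcdhb13 (1.41), with a list median of 0.52 that became -0.023 with transduction-list scaling.

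Transduction genes were higher in Olfr73 for 7 of 23 and lower for 0, with Gnb1 (1.62) and Slc12a2 (1.26). Omp was 0.59 higher (edgeR adjusted p = 0.0435), a call lost with RLE scaling, with replicate blocks, with only the 6 libraries compared, with Olfr160 library 3 alone, with transduction-list scaling and when any library other than Olfr160 library 3 was left out (adjusted p 0.0551 to 0.125). Omp belongs to the transduction list, so the loss of its call with that scaling is partly set by construction. Cilia genes were higher for 16 of 33 and lower for 0 (10 and 1 with library size alone, 0 and 2 with transduction-list scaling), including Dync2h1 (0.92). Ion channel genes were higher for 10 of 24 and lower for 2 (3 and 3 with transduction-list scaling), including Scn9a (1.15) and Kcna2 (1.34). Synapse genes were higher for 9 of 23 and lower for 2 (3 and 3 with transduction-list scaling), including Cacna1b (1.07). The cilia median of 0.47 became -0.061 with transduction-list scaling. Immediate early genes were higher in Olfr160 for 9 of 25, with Fos at 1963 ± 508 against 795 ± 116 in Olfr73, Arc at 45.4 ± 15.6 against 11.8 ± 4.88 and Ier3 at 55.6 ± 21.05 against 14.8 ± 5.20. Sustentacular and gland markers were higher in Olfr160 for 21 of 26, with Sec14l3 at 8210.5 ± 2212 against 1689 ± 433. Basal and progenitor markers were higher there for 11 of 16, with Neurod1 (-2.13) and Mcm2 (-2.12), microvillar and brush markers for 7 of 11 and lower there for 1, with Coch (-2.09), and immune markers for 8 of 19, with H2-Aa (-2.81). Respiratory markers were higher in Olfr160 for 4 of 10, red blood cell markers for 4 of 7 and glia, stroma and vessel markers for 3 of 16, with Dcn at -2.22. Of 112 symbols beginning with Rpl or Rps 17 were higher in Olfr160 and 4 in Olfr73 (25 and 4 with library size alone, 46 and 0 with transduction-list scaling), with Rpl10 at -0.98. Of 697 odorant and trace amine receptors 101 were higher in Olfr160.

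The genes with the largest changes included Serinc3, a membrane carrier of the serine incorporator family, at 387 ± 71.2 in Olfr73 and 19.1 ± 18.6 in Olfr160, Aspg (69.7 ± 19.8 against 6.57 ± 2.82), Dusp26 (21.3 ± 11.6 against 1.49 ± 0.509) and Col27a1 (2.99). On the side of Olfr160 were the collagenase gene Mmp13, at least 436-fold higher against 0 counts in Olfr73, Dmbt1 (-9.23) and the long noncoding RNA Miat (-5.37), of which Mmp13 and Dmbt1 did not pass with limma-voom. Unfolded protein response genes were divided, 2 higher and 3 lower in Olfr73 of 32 (2 and 5 with library size alone, 0 and 10 with transduction-list scaling), with Ddit3 (1.08) and Pdia6 (-0.82) on either side, as were heat shock genes, 3 higher and 3 lower of 12. Olfactory transcription factors were higher for 3 of 18 and lower for 3, immature neuron markers higher for 3 of 19 and lower for 7, vomeronasal and atypical markers higher for 1 of 18 and lower for 2, and mitochondrially encoded genes neither way for 14 of 14. Of 10 strain-variable genes 2 were higher in Olfr73, among them the insulin-degrading enzyme gene Ide (0.85), and 3 were lower. Atf5 stood at 17.2 ± 1.51 against 11.1 ± 3.31 and did not pass (edgeR adjusted p = 0.168), and of the 6 tested genes of the list of Y-linked genes and Xist 0 passed. Adjusted over the list alone, 8 transduction genes and 22 cilia genes were higher in Olfr73, and 24 sustentacular and 11 immediate early genes were higher in Olfr160. The median and the mean differed in sign for the local sorting (0.16 and -0.23), synapse (0.64 and -0.22), heat shock (0.14 and -0.24) and transcription factor lists (0.052 and -0.23). Camera called 17 lists with the preset correlation and 0 with an estimated one, where the lowest adjusted p = 0.472.

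Asked over the whole design, 8333 genes differed among the 3 groups (edgeR quasi-likelihood F test on both coefficients, adjusted p below 0.05), and 4366 did with Olfr160 library 3 alone. On the first principal component, which held 64.5% of the variance, the Olfr160 libraries lay at -159.4 to -112.9, the Olfr73 libraries at -30.7 to 23.4 and the Olfr1507 libraries at 129.0 to 170.4, in the order of the share of the tagged receptor. Within each group the libraries kept this order too, with shares of 2.08% to 10.1%, 22.8% to 32.8% and 85.1% to 94.7%. The component therefore cannot be read as a separation by receptor identity alone. A gene was counted as set apart in a group when it passed in both of that group's comparisons with the same direction. Olfr1507 set apart 1854 genes as higher and 2549 as lower, Olfr160 set apart 1353 and 753, and Olfr73 set apart 336 and 293. Calb2 was set apart as higher and Nqo1, Acsm4 and Robo2 as lower in Olfr1507, and Serinc3 as higher in Olfr73. Independent lists of the same sizes would overlap by 493 and 903 genes for Olfr1507, 475 and 253 for Olfr160 and 243 and 249 for Olfr73. The comparisons of a group share its 3 libraries, which are too few to split between the comparisons, so part of the excess may come from the shared libraries. With Olfr160 library 3 alone the counts were 2670 for Olfr1507, 40 for Olfr160 and 27 for Olfr73, and without Olfr160 library 2 they were 714 for Olfr160 and 233 for Olfr73, while Olfr1507 without its library 1 gave 2925.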

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

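Of the tests below, those with Olfr160 library 3 alone, with transduction-list scaling and with thinning were chosen after the result was seen. Genes differing numbered 7939 (Olfr1507 vs Olfr160), 5640 (Olfr1507 vs Olfr73), 2936 (Olfr73 vs Olfr160) and 8333 (among the 3 groups), and genes set apart 629, 4403 and 2106 (Olfr73, Olfr1507, Olfr160). Under the alternatives that left them within 1.5 times, 13 of 18, 15 of 18, 13 of 18 and 13 of 16 for the counts of genes differing, they ranged from 5413 to 8682, 4385 to 7358, 2069 to 4209 and 6106 to 11828. Those for genes set apart (11, 12 and 12 of 16) ranged from 525 to 755, 3110 to 5217 and 1813 to 2928.

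With a 2-fold minimum the counts were 5147, 3533, 1693 and 5450, with 260, 2782 and 1275 set apart. With an adjusted p below 0.01 they were 4969, 2837, 769 and 4868, with 143, 2218 and 573 set apart. These thresholds call fewer genes by construction, as does glmTreat against 2-fold (3435, 1774 and 172). With limma-voom 4453 genes differed between Olfr73 and Olfr160 and 3347 were set apart in Olfr160, and with DESeq2 945 were set apart in Olfr73. The cause was not tested. Olfr160 library 3 alone, with the spread of the other groups assumed for the lone library, gave 3337 genes (Olfr1507 vs Olfr160), 61 (Olfr73 vs Olfr160), 4366 among the 3 groups and 27, 2670 and 40 set apart. Scaling to the transduction list gave 12524 genes for Olfr1507 vs Olfr160, 283 set apart in Olfr73 and 6840 in Olfr1507, and by construction moved the median of all genes. Of camera lists, 14, 14 and 17 were called, 9 and 7 (both comparisons of Olfr1507, with Olfr160 first) with transduction-list scaling, 9 for Olfr1507 vs Olfr73 with library size alone, and 0, 0 and 0 with an estimated correlation. With fry 18, 11 and 14 lists were called. With TPM the share of the tagged receptor in Olfr73 was 47.2%, against 26.4% by counts, and in Olfr160 3.44%, against 5.58%. The cause was not tested.

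Leaving out each library in turn gave 6391 to 8890, 3657 to 5546, 976 to 3062 and 6471 to 8832 genes differing, 233 to 615, 2925 to 4455 and 714 to 2295 set apart, 13 to 15, 12 to 15 and 17 to 20 lists, and shares of 23.2 to 28.2%, 88.4 to 93.2% and 3.31 to 7.32% (Olfr73, Olfr1507, Olfr160). The counts moved by over 1.5 times without Olfr1507 library 1 (3657 and 2925 set apart in Olfr1507), without Olfr160 library 1 (1408, with 383 set apart in Olfr73 and 971 in Olfr160), without Olfr160 library 2 (976, 233 and 714) and without Olfr73 library 3 (1878 and 376). The same library numbers did not pair the samples (correlations of -0.19 to 0.13), and with the number as a block the counts were 7398 (genes differing, Olfr1507 vs Olfr160), 4804 (genes differing, Olfr1507 vs Olfr73), 2485 (genes differing, Olfr73 vs Olfr160) and 7571 (genes differing among the 3 groups).

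Of 333 gene values 311 were called, and 265 of these were called in each of the 9 fits without a library, while 46 were lost in at least 1. In 29 values the sign changed in at least 1 alternative, 13 of them called, 0 of these outside transduction-list scaling. Transduction-list scaling turned, for Olfr1507 vs Olfr160, the log2 fold changes of Nfia to -0.64, Pcdhb17 to -0.35, Hsp90ab1 to -0.16, Bbs1 to -0.26, Ift172 to -0.18, Scn9a to -0.33, Rps6kc1 to -0.25, Olfr73 to -0.76, Omp to -0.094, Ncam2 to -0.35, Olfr1372-ps1 to -0.30 and Olfr1280 to -0.58. For Olfr1507 vs Olfr73 it turned Ift52 to -0.077, Rpl7l1 to -0.028, Omp to -0.19 and Olfr1206 to -0.49. For Olfr73 vs Olfr160 it turned Bbs1 to -0.010, Adcy3 to -0.18, Nqo1 to -0.29, Kirrel2 to -0.13, Kirrel3 to -0.34 and Olfr169 to -0.18. Omp and Adcy3 are members of the list used for scaling, so their values there are partly set by construction. With Olfr160 library 3 alone, for Olfr73 vs Olfr160, Adcy3 was -0.070, Nqo1 -0.41, Nrp1 -0.022, Kirrel3 -0.40, Olfr1349 0.13 and Olfr1372-ps1 0.15.

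The other sign changes were in values not called. For Olfr1280 (Olfr1507 vs Olfr160), Olfr1206 (Olfr1507 vs Olfr73) and Olfr169 (Olfr73 vs Olfr160) the values were -1.10, -1.65 and -0.13 with TPM and a pseudocount of 0.1, -0.18, -0.72 and -0.11 with a pseudocount of 1, -1.41, -1.43 and -0.037 with limma-voom and -1.50, -0.088 and -0.21 with the block, and Olfr1206 was -0.031 with library size alone. Without each library in turn, values that changed sign ranged, for Olfr1507 vs Olfr160, from -0.16 to 0.77 for Olfr73 and -1.98 to 1.45 for Olfr1280, both negative (-0.16 and -1.98) without Olfr1507 library 2. For Olfr1507 vs Olfr73 they ranged from -1.14 to 0.87 for Olfr1206 and -1.49 to 2.24 for the log2 fold change of Olfr1280, Olfr1507 vs Olfr73, both negative without Olfr1507 library 2, and -2.42 to 0.40 for the log2 fold change of Olfr160, Olfr1507 vs Olfr73, positive without Olfr73 library 2. For Olfr73 vs Olfr160 they ranged from -0.11 to 0.53 for Nqo1, negative without Olfr160 library 1, -0.19 to 0.47 for Kirrel3, negative without Olfr160 library 1 (-0.070) or Olfr73 library 1, -0.097 to 0.58 for Kirrel2, negative without Olfr73 library 2, -0.67 to 0.15 for Efna5, positive without Olfr160 library 3 or Olfr73 library 2 (0.071), -0.60 to 0.97 for Olfr169, negative without Olfr73 library 2, and -1.40 to 0.092 for Olfr1280, positive without Olfr73 library 1. The cause was not tested. Calls lost were 100 with Olfr160 library 3 alone, 43 with transduction-list scaling and 38 without Olfr160 library 2. With 3 libraries per group the simulated test called 24% of genes changed 2-fold. Only 200 genes were changed there, so its Benjamini-Hochberg cutoff was stricter than in the data. The 24% therefore does not measure the share of real changes called here. A missing call does not show that a gene is unchanged.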

Other observations

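Tests chosen after the result was seen were those of dorsal zone, local sorting and activity genes against RNA of cells that are not neurons and of the tagged loci on their own base rates, the share of receptors in the class I region, and the genes singled out below for their levels. The 4 other tests of an explanation were written after the receptor shares were seen and before their own values were.

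The Olfr160 libraries differed in the share of the tagged receptor, 2.08%, 4.54% and 10.1%, and held more counts on markers of other cells than the other groups. If RNA from other cells raised genes in Olfr160, these should be lower in library 3, with the highest share, than in library 1. Over 4008 genes other than Olfr genes higher in Olfr160 than in Olfr1507 the median log2 ratio of library 3 to library 1 was -0.62, below the 5th percentile of expression-matched random lists (-0.25), so RNA from cells other than the labelled neurons may raise many of them. For 3397 genes higher in Olfr1507 the ratio was 0.26, between the bounds set beforehand, and dilution by such RNA cannot be told apart from a difference between the neurons. Over 20 dorsal zone, local sorting and activity genes higher in Olfr160 the ratio was 0.50, with 16 above 0, the outcome stated for a source other than cells that are not neurons. It rests on 1 library over 1 other, was not set beside random lists, and lies below the 0.82 of transduction genes. A partial contribution of such cells therefore cannot be decided. The ratio of odorant and trace amine receptors was -0.35, with 414 of 697 below 0. RNA from neurons with other receptors stays open, as does receptor identity, which was not tested apart from it.

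Within Olfr160 the lists differed in direction, with median log2 ratios of library 3 to library 1 of 0.82 for transduction, 0.70 for dorsal zone and 0.85 for activity-dependent genes, -0.37 for ventral zone genes (5 of 6 below 0), -0.82 for sustentacular and gland, -1.35 for respiratory and -0.88 for immune markers, and -0.76 for immediate early and -0.55 for ribosomal genes. For glia, stroma and vessel markers it was -0.11, with 9 of 16 below 0. Of 4540 genes higher in Olfr160 than in Olfr1507, 94.2% were called again after all libraries were thinned to 17212782 counts, a test with little room to fail, since the Olfr160 libraries held fewer counts on average than those of Olfr1507.

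Pooled over the tagged receptor loci, genes within 10 Mb were set apart more often than others (odds ratio 1.61, Fisher p = 0.000277). The planned test had been stated for genes called in the comparisons of the receptor. Other genes were set apart at 4.03% for Olfr73, 26.5% for Olfr1507 and 12.8% for Olfr160. The pooled ratio mixes these rates, so it can rise without any enrichment near a locus. In a test stratified by locus the odds ratio was 1.297 (exact p = 0.0455). A chromosome segment carried along with the tagged allele may contribute, but neighbouring genes are not independent. By locus the odds ratio was 1.84 at Olfr160 (26 of 122 genes near it were set apart, Fisher exact p = 0.00933), 1.24 at Olfr73 (Fisher exact p = 0.570) and 1.11 at Olfr1507 (Fisher exact p = 0.559). Of 14784 windows over the genome 2.22%, 22.4% and 32.3% had as high a share. Receptor identity near the loci cannot be separated from such a segment here.

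With 3 libraries against 3 the 10 splits are too few for a share under 0.05. The real splits gave 7939, 5640 and 2936 genes (Olfr1507 vs Olfr160, Olfr1507 vs Olfr73, Olfr73 vs Olfr160) and the highest other splits 0, 0 and 1, so that 1 split of 10 gave as many in each. For lists the real counts were 14, 14 and 17 and the highest others 15, 11 and 18, with 2, 1 and 3 of 10 splits as large. Of 100 splits of the 9 libraries only the real one gave as many genes differing among the 3 groups (8333, highest other 3885). Only the real one gave a group with as many set apart as Olfr1507 (4403, highest other 3372). The libraries of a group may be technical replicates, so these splits show only that libraries with the same label resemble each other. They cannot tell receptor identity from sort purity or batch, and chance differences between animals were not tested. For Olfr73 (629) and Olfr160 (2106) 4 splits gave a group with as many (highest other 3372). Of these 4 the 3 other than the real one kept Olfr1507 whole and gave 3145 to 3372, so they say little on the counts of Olfr73 and Olfr160 themselves. The 2 splits that kept Olfr160 whole gave 60 to 78 set apart and at most 354 genes differing, the 4 that kept Olfr73 whole 1 to 2 and at most 4, and the 90 that kept no group whole 0.

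Several genes had levels that differed many-fold between at least 2 of the groups (normalised CPM means in the order Olfr73, Olfr1507, Olfr160, n = 3). Serinc3 stood at 387, 20.0 and 19.1, and Mmel1 at 22.7, 0.278 and 2.06. Vstm2a stood at 2.73, 134 and 24.1, and Dnaic2 at 10.5, 422 and 44.6. Adcy5 stood at 0.295, 69.9 and 3.75, Cidea at 10.2, 319.7 and 26.6, and Papss2 at 354.8, 2.58 and 227. Eno1b (37.7, 250.3 and 700.5) and Vcp-rs (23.2, 373.7 and 24.2) have close relatives in the genome, and reads shared with these were not examined. Class I receptor genes in a region of chromosome 7 with 156 Olfr genes took part of the counts on receptors other than the 3 tagged ones. Their shares were 5.17 ± 0.951%, 5.14 ± 2.97% and 4.37 ± 0.590% (mean ± SD, n = 3). The libraries of the groups overlapped, and the difference was not tested.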
